A study of Mus musculus with 9 samples.

How the data were processed

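Libraries were made with an mRNA library kit from RNA isolated with TRIzol from mouse BMMs and sequenced on a DNBSEQ-T7, per the labels' protocols. The deposited table held raw read counts per gene symbol for 9 libraries, and the authors' processing notes name Trimmomatic 0.36, FastQC 0.11.2, HISAT2 2.1.0 and DESeq2 1.12.4, per the submitters' processing notes. These notes also list the builds GRCh38 and mm39 with no role, of which GRCh38 is a human build. The counting program, the annotation and the strand setting were not given in the sources used here, so genes that overlap, lie antisense to each other or have near-identical copies are uncertain.

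The table had 51826 rows, of which 26492 had a count in any library. On 183 rows the symbol was shared with another row (91 symbols), and such rows were kept apart. It had 0 rows without a gene name and 0 columns without a sample. Every column carried a library name that the labels give for 1 sample. No coordinates are given, because the table held none and the build named in the notes was not used here. Transcript length and GC content were taken from the longest transcript of each symbol in GENCODE vM21 (assembly GRCm38) and used for no other purpose.

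Depth ran from 43084296 to 50407973 counts per library. Within groups the chi-square per degree of freedom between libraries was 28.81 to 488.65, so no library was a copy of another, and the correlation of log2 CPM was 0.919 to 0.986. Genes were kept by edgeR's filterByExpr, which left 15429, and scaled by TMM. Differences were tested in R 4.3.3 with edgeR 4.0.16 (glmQLFit with its default setting and glmQLFTest), all 9 libraries in 1 fit by group, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. The fits had first been run with the option legacy = FALSE and its counts had been seen before the package default was taken as the main setting; counts under that option are given with the alternatives. The SE of a fold change was its size divided by the square root of the F statistic.

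The comparisons were CM against control, CM plus DTM against CM and CM plus DTM against control. A set of 34 gene lists for macrophage functions, cell states, other cell types and RNA quality was fixed before the data were examined, as were the comparisons, the tests, the rule for named genes and all alternatives except those listed at the end. Lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01. Of 34 lists, camera called 16 in CM against control, 10 in CM plus DTM against CM and 11 in CM plus DTM against control, and with the correlation estimated from the data it called 0 in each. Members were also adjusted over the list alone.

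Named genes were Ifit1 and Cx3cr1, and per comparison the 8 largest rises and 8 largest falls (5 and 5 for CM plus DTM against control) among called genes with a mean of at least 5 CPM and groups that did not overlap. From each list up to 4 called members with a mean of at least 1 CPM could be named, or for a list with none, up to 2 of its most abundant members as values. Predicted genes and unnamed clones were counted and not named. A gene that the rule names is not reported here, and the counts include it.

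The tests were tried on counts simulated from the real means, with 200 genes changed and 15133, 15182 and 15120 genes tested for the comparisons in the order below. Of the genes changed by a log2 fold of 2, 66% were recovered for CM against control, 65% for CM plus DTM against CM and 67% for CM plus DTM against control, and of those changed by 1, 9%, 7% and 9%. Each run made 3, 7 and 3 false calls. These counts were drawn gene by gene with no library that stood apart, so such recovery need not hold for the real libraries. Libraries shared between comparisons were treated with 100 simulations each, in which CM plus DTM equalled CM, or both treated groups equalled control.

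Alternatives were DESeq2 1.42.0, limma-voom, other scaling, other count filters, fits of the compared groups only, library numbers as a block, a minimum fold and each library left out in turn. Chosen after seeing the data were legacy = FALSE, limma-voom with sample weights, and fits without the libraries that stood apart (CM 1 and CM plus DTM 1).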

Results

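RNA was measured in mouse bone marrow-derived macrophages (BMMs), which are macrophages grown from bone marrow precursors in culture. The study had 3 groups of 3 libraries each: untreated BMMs (control), BMMs kept for 48 h in medium conditioned by K7M2 cells (CM), and BMMs kept for 48 h in that medium together with DTM (CM plus DTM). K7M2 is a mouse osteosarcoma cell line, and conditioned medium carries what such cells release. The labels do not say what DTM stands for, and give no culture time or medium for control, so differences from control may include those of time and medium. The values were raw counts per gene symbol. The control libraries held 48976788, 49532150 and 43084296 counts, the CM libraries 50407973, 44921305 and 47907455, and the CM plus DTM libraries 44434428, 47644645 and 47335168. Nothing in the labels says that the 3 libraries of a group came from separate cultures or animals, so the p-values measure only the spread between these libraries, which may be technical. Levels are given as CPM, read counts scaled to the size of the library, as mean ± SD with n = 3, and fold changes on the log2 scale with their standard error (SE).

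The comparison of CM with control asked how the tumour cell medium changed macrophages, with Ifit1 and Cx3cr1 named in the title of the series. Ifit1, an interferon-induced antiviral gene, rose from 0.796 ± 0.0568 CPM in control to 25.3 ± 5.56 CPM in CM. Cx3cr1, the receptor of the chemokine fractalkine, fell from 76.1 ± 49.5 to 0.407 ± 0.114 CPM. Interferon-stimulated genes rose almost as a block, and the chemokines Ccl3 and Ccl6, the metalloproteinases Mmp12 and Mmp13, the fatty acid binding proteins Fabp4 and Fabp5 and the checkpoint ligand Cd274 (PD-L1) rose as well. Among the genes that fell were the receptors Fcrls, Gpr84 and Gpr183 and the growth factor gene Pdgfb.

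The log2 fold change of Ifit1 was 4.98 (SE 0.90, adjusted p = 0.0148) and that of Cx3cr1 was -7.53 (SE 0.88, adjusted p = 0.00263). Both genes lay apart in all 6 libraries of the comparison. The call of Ifit1 was lost when control 1, 2 or 3 was left out (adjusted p = 0.0853, 0.0769 and 0.07), with the fold change between 4.81 and 5.13 over the 9 fits that each lacked a library. The call of Cx3cr1 held in all 9 of them.

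**Figure D1:**
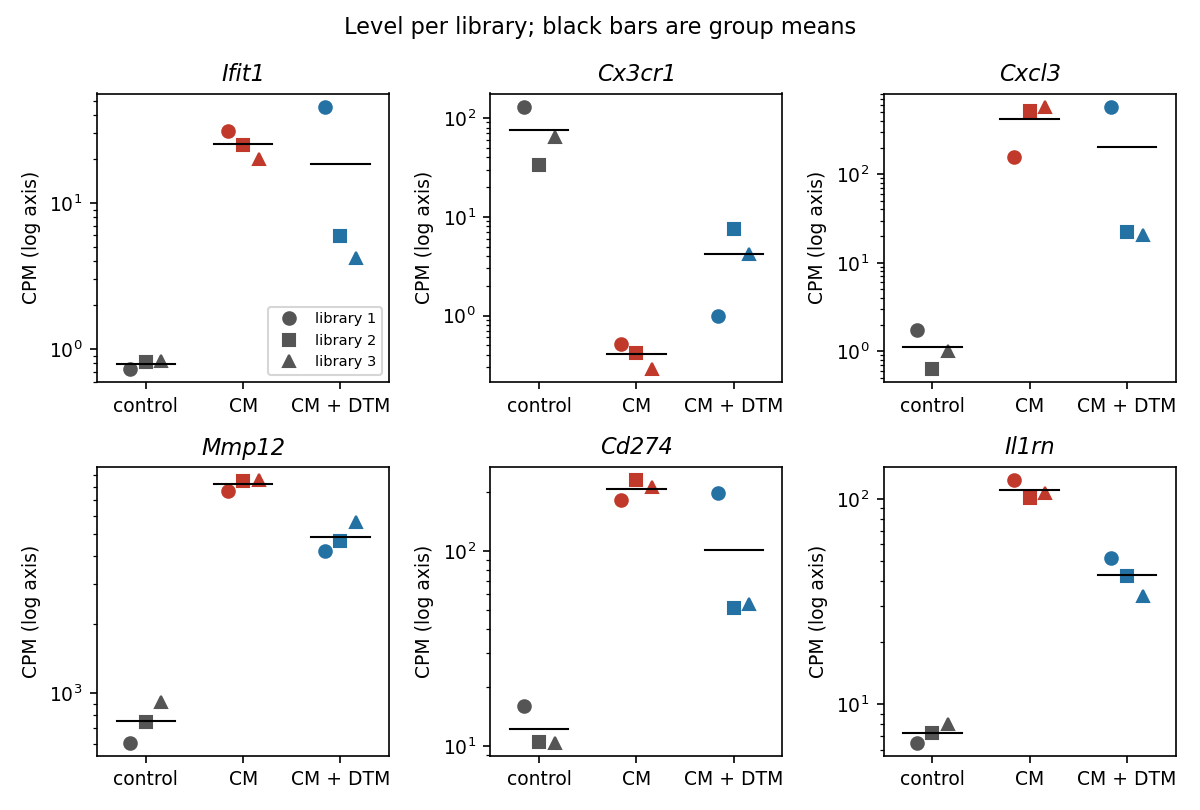
CPM of 6 genes on a log axis in each of the 9 libraries, with symbols for library numbers and black bars for group means (n = 3 per group). Ifit1 had a mean of 25.3 CPM in CM and lay at 45.8, 5.96 and 4.23 CPM in CM plus DTM 1, 2 and 3.

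The largest rises in log2 fold change were those of Cxcl3 (8.54), Mgl2 (7.70), Slfn1 (7.32), Ppbp (6.84), Ifi206 (6.82), F5 (6.76), Ifi213 (6.60) and Mmp13 (6.53). Cxcl3 and Ppbp are chemokines that attract neutrophils, Mgl2 is a lectin of alternatively activated macrophages, F5 encodes coagulation factor V and Mmp13 is a collagenase. F5 was uneven in CM, at 48.2 ± 60.8 CPM against 0.441 ± 0.141 CPM in control. It stood at 118, 14.9 and 11.4 CPM in CM 1, 2 and 3. Of these rises, F5 and Mgl2 were highest in CM 1 and the others lowest in it, so their order rests partly on that library. The largest falls besides Cx3cr1 were those of Nptx1, Fcrls (-5.05), Notch4 (-4.60), Cspg4 (-4.09), Gpr84 (-3.99), Gpr183 (-3.85) and Nanos1 (-3.78). Nptx1 fell from 20.8 ± 22.1 CPM to 0.0295 ± 0.0511 CPM, a level of hardly any counts, so no fold is given for it. All of these falling genes were highest in control 1, such as Notch4 at 36.2, 10.3 and 7.33 CPM in control 1, 2 and 3. The sizes of their falls thus rest partly on that library, although their calls held in all 9 fits that each lacked a library. The calls of Cxcl3 (adjusted p up to 0.0856) and Ppbp (up to 0.148) were lost without control 1, 2 or 3, and that of Ppbp also without CM 2 or 3. Slfn1, Ifi206, Ifi213, Mgl2 and Fcrls belong to families of similar genes, and reads may have been divided among their members.

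Of the 54 interferon-stimulated genes tested, 50 rose, 0 fell and 4 were not called, and 53 rose when adjusted over the list alone. The list holds Ifit1, which the study chose on these samples and which is not independent evidence of the direction. Slfn1, Ifi213 and Ifi44 (log2 fold change 5.84) led it. The list test gave adjusted p = 5.54e-46 with the preset correlation, and adjusted p = 0.166 with an estimated correlation. Of 24 genes typical of interferon gamma, among them the GTPases Gbp6 (5.71) and Iigp1 (4.95), 17 rose and 0 fell, and 20 rose when adjusted over the list alone (list test adjusted p = 5.95e-19; adjusted p = 0.112 with an estimated correlation). Without CM 1, CM plus DTM 1 or both, libraries that stood apart from their groups, 46, 53 and 53 interferon-stimulated genes rose. The list was not counted without control 1, 2 or 3, where 208, 182 and 235 genes of any kind rose, against 623 with all libraries.

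Of 32 NF-kB target genes 9 rose and 0 fell, and 16 rose when adjusted over the list alone (list test adjusted p = 7.6e-07; adjusted p = 0.35 with an estimated correlation). Il1a rose by a log2 fold change of 5.99, Il1rn, the natural antagonist of interleukin 1, by 3.93 (SE 0.21), and the chemokine Ccl3 by 3.85. Of 28 chemokines and their receptors, 12 rose and 1, Cx3cr1, fell, and 17 rose and 4 fell when adjusted over the list alone (list test adjusted p = 5.46e-05; adjusted p = 0.457 with an estimated correlation). The list contains Cx3cr1, so it is not independent of the study's choice. Ccl6 rose from 455 ± 21.9 to 15100 ± 4980 CPM. Without CM plus DTM 1, 16 NF-kB genes rose, and 16 chemokine genes rose and 4 fell.

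In the alternative activation list of 20 genes 8 rose and 0 fell, with 9 up and 1 down when adjusted over the list alone (list test adjusted p = 0.000678; adjusted p = 0.169 with an estimated correlation). Arg1, which consumes arginine, rose by a log2 fold change of 3.40 and the glucan receptor Clec7a by 3.25. In the lipid-associated and tumour-associated list of 26 genes 9 rose and 0 fell, with 13 up and 2 down when adjusted over the list alone (list test adjusted p = 4.98e-05; adjusted p = 0.198 with an estimated correlation). Mmp12, macrophage elastase, rose from 754 ± 153 to 8250 ± 509 CPM, and Fabp4 (3.09), Fabp5 (2.30) and Spp1 (2.26) rose as well. Of 18 checkpoint and suppressive ligand genes 7 rose and 1 fell, with 10 up and 3 down when adjusted over the list alone (list test adjusted p = 0.00415; adjusted p = 0.224 with an estimated correlation). Cd274 rose by a log2 fold change of 4.08 (SE 0.54) and Cd200r1 by 2.12, and the gene that fell was the inhibitory receptor Siglece (-2.10), named after its values were seen. Without control 1, 2 or 3 the calls of Arg1 (adjusted p up to 0.133) and Cd200r1 (up to 0.0759) were lost, and that of Arg1 also without CM 2 or 3. That of Siglece was lost without control 1, 2 or 3 or CM 1 or 2 (up to 0.0986). Without CM plus DTM 1, 3 checkpoint genes fell. Of 33 matrix remodelling and growth factor genes 9 rose and 2 fell, with 10 up and 2 down when adjusted over the list alone, and the list was not called (list test adjusted p = 0.212; adjusted p = 0.764 with an estimated correlation), although it was without CM 1 (adjusted p = 0.0131).

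In the lysosome list of 35 genes 7 rose and 0 fell, with 19 up and 1 down when adjusted over the list alone (list test adjusted p = 4.86e-06; adjusted p = 0.112 with an estimated correlation), and the cathepsin Ctsz rose by a log2 fold change of 1.18. Of 19 osteoclast genes 4 rose and 1 fell, with 7 up and 1 down when adjusted over the list alone (list test adjusted p = 0.00773; adjusted p = 0.224 with an estimated correlation). Atp6v0d2, a proton pump subunit, rose by 3.10 and the protease Ctsk by 1.42. The gene that fell was Tnfrsf11a (-0.99), the receptor RANK, named after its values were seen, and its call was lost without any 1 library except CM plus DTM 1 and 2 (adjusted p up to 0.122). Of 36 genes of the amino acid and integrated stress response 5 rose and 0 fell, with 8 up and 1 down when adjusted over the list alone (list test adjusted p = 0.000275; adjusted p = 0.224 with an estimated correlation), including Atf5 (1.67). Of 23 genes of the unfolded protein response 2 rose and 0 fell, with 3 up when adjusted over the list alone (list test adjusted p = 0.0148; adjusted p = 0.169 with an estimated correlation), and without CM 1 that list was not called (adjusted p = 0.0516). Without CM plus DTM 1, 16 lysosome genes and 9 stress response genes rose, and without CM 1, 11 lysosome genes. Abcg1, a cholesterol exporter, rose by 4.40, although its list of 20 liver X receptor targets had 3 rises and was not called (list test adjusted p = 0.0715).

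Of 25 genes of the NRF2 antioxidant response 0 rose and 5 fell, with 1 up and 5 down when adjusted over the list alone (list test adjusted p = 0.0347; adjusted p = 0.224 with an estimated correlation), among them Gsta3 (-2.21) and Gclc (-1.07). Of the 42 proliferation genes 0 were called by either count, with a median log2 fold change of -1.18 (list test adjusted p = 4.86e-06; adjusted p = 0.642 with an estimated correlation). Pcna stood at 555 ± 35 CPM in control and 348 ± 126 in CM. Without CM plus DTM 1, 11 proliferation genes fell, and without it and CM 1, 18. Oxidative phosphorylation genes (33, median -0.18) and cholesterol synthesis genes (26, median -0.40) had 0 calls by either count (list test adjusted p = 0.0148 and 0.01; adjusted p = 0.691 and 0.642 with an estimated correlation), and without CM 1 the former list was not called (adjusted p = 0.206), while 8 cholesterol synthesis genes fell without CM plus DTM 1. The 27 mesenchymal genes, which osteosarcoma cells also express, had 0 calls and a median of -0.45 (list test adjusted p = 0.00415; adjusted p = 0.691 with an estimated correlation), which became 0.01 without CM 1 (adjusted p = 0.873). Relative to the control mean on the log2 scale, the median of that list lay at -2.70 in CM 1, that of the neutrophil list at -4.43 and that of the proliferation list at -2.04. The neutrophil list of 19 genes had 1 rise, the collagenase Mmp8 (3.74), which macrophages also express, and was not called (list test adjusted p = 0.0981).

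By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 865 of 15429 genes changed, 623 up and 242 down, and the groups did not overlap for 36.7% of the genes tested, where chance gives 10%. The share of genes without overlap was 34.4% in CM plus DTM against CM and 34.5% in CM plus DTM against control. The count of changed genes was 276, 256 and 317 without control 1, 2 and 3, and 353 and 413 without CM 2 and 3. It was 1884 without CM plus DTM 1 and 1937 by DESeq2. With total count scaling, which moved the median of all genes to -0.21, 415 genes rose and 464 fell.

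**Figure D2:**
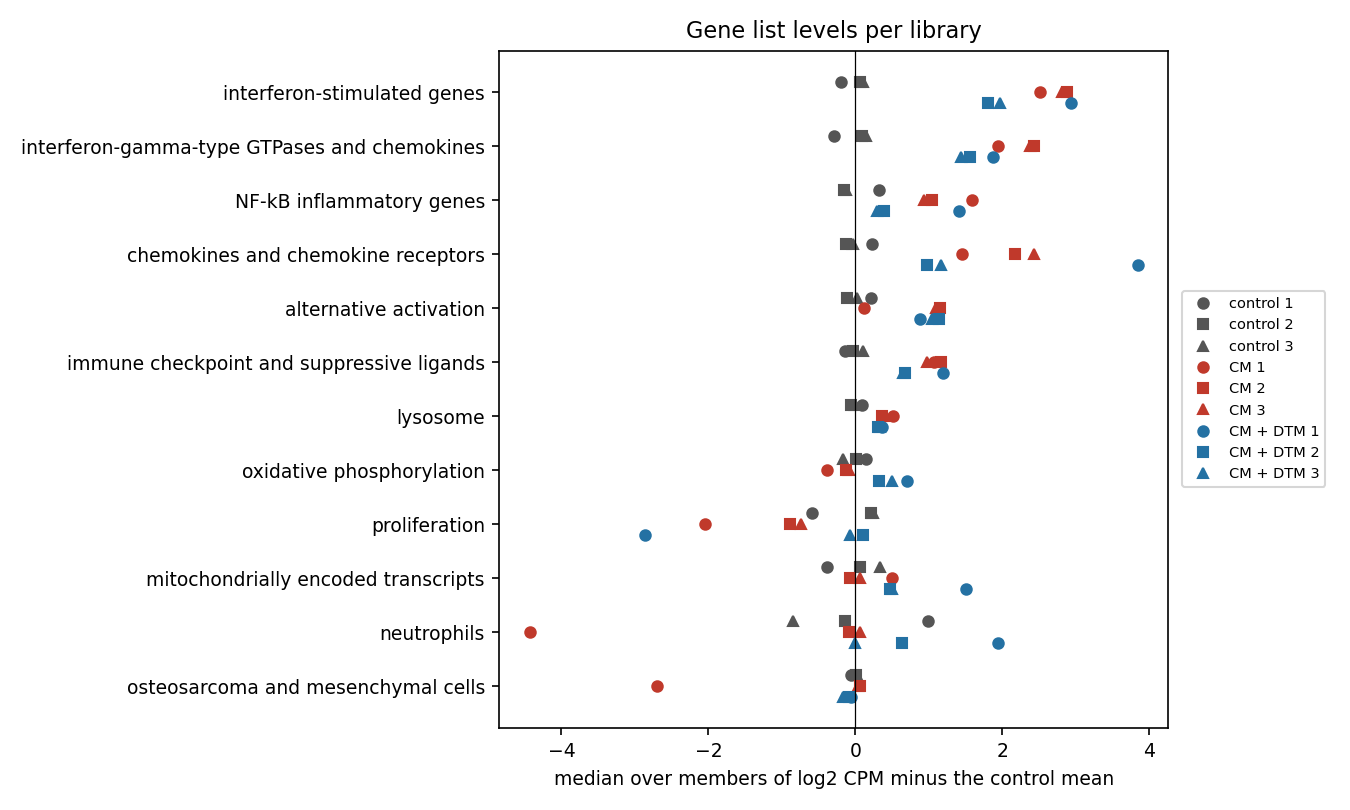
Median over the members of 12 gene lists of log2 CPM minus the control mean, 1 symbol per library (9 libraries; colour gives the group, shape the library number). Interferon-stimulated genes lay at 2.52, 2.88 and 2.81 in CM and at 2.94, 1.81 and 1.97 in CM plus DTM; CM 1 was lowest for neutrophil genes at -4.43.

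The comparison of CM plus DTM with CM asked what DTM added to the medium changed. No gene passed the threshold. Cx3cr1 stood at 4.22 ± 3.23 CPM in CM plus DTM against 0.407 ± 0.114 CPM in CM, a log2 difference of 3.36 (SE 0.76, adjusted p = 0.0611), and was higher in all 3 libraries. Ifit1 stood at 18.6 ± 23.5 CPM against 25.3 ± 5.56 CPM, a difference of -0.44 (SE 0.75, adjusted p = 0.735), with CM plus DTM 1 above every CM library and CM plus DTM 2 and 3 below every one. As a list, oxidative phosphorylation genes were higher with DTM, and interferon-stimulated, NF-kB, osteoclast and liver X receptor genes were lower, by a test that was lost for every list with an estimated correlation. CM plus DTM 1 ran the other way for interferon-stimulated genes, above every CM library, and for NF-kB genes lay above CM 2 and 3.

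Without CM plus DTM 1 the difference of Ifit1 was -2.36 (adjusted p = 0.0388), and without CM plus DTM 3 it was 0.05 (adjusted p = 0.973). Without CM plus DTM 2 that of Cx3cr1 was 2.68 (adjusted p = 0.0476). Over the 9 such fits Cx3cr1 lay between 2.68 and 3.78.

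Of the 33 oxidative phosphorylation genes 0 were called over all genes and 26 rose when adjusted over the list alone, with a median difference of 0.73 (list test adjusted p = 3.14e-11; adjusted p = 0.786 with an estimated correlation). Atp5a1, a subunit of ATP synthase, stood at 744 ± 34.7 against 534 ± 84.2 CPM. The list median was 0.54 without CM plus DTM 1 and 0.65 without CM 1. The 15 mitochondrially encoded transcripts had 0 calls by either count and a median of 0.68 (list test adjusted p = 0.0383; adjusted p = 0.984 with an estimated correlation), with CM plus DTM 1 the highest library at 1.51 above the control mean. Without that library the list was not called (median 0.28, adjusted p = 0.185). Of 25 NRF2 response genes 0 were called and 2 rose when adjusted over the list alone, with a median of 0.23 (list test adjusted p = 0.0383; adjusted p = 0.786 with an estimated correlation), which was 0.35 without CM 1.

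Of the 54 interferon-stimulated genes 0 were called and 3 fell when adjusted over the list alone, with a median of -0.25 (list test adjusted p = 0.0136; adjusted p = 0.984 with an estimated correlation), which was -0.89 without CM plus DTM 1. Relative to the control mean that list lay at 2.94 in CM plus DTM 1, above the 2.52, 2.88 and 2.81 of CM, and at 1.81 and 1.97 in CM plus DTM 2 and 3. It holds Ifit1, chosen by the study on these samples. Its most abundant members had other values, Bst2 728 ± 240 CPM in CM and 967 ± 534 in CM plus DTM, and Ifi27l2a 393 ± 66.7 and 562 ± 216 CPM. The log2 difference of Bst2 was 0.41, and -0.19 without CM plus DTM 1. For the interferon gamma genes 5 of 24 fell when adjusted over the list alone, with a median of -0.46 (list test adjusted p = 0.0168; adjusted p = 0.964 with an estimated correlation), which was -0.85 without CM plus DTM 1. For the NF-kB genes 4 of 32 fell when adjusted over the list alone, with a median of -0.41 (list test adjusted p = 0.0383; adjusted p = 0.984 with an estimated correlation), which was -1.03 without CM plus DTM 1, and without CM 1 that list was not called (median -0.11, adjusted p = 0.0724). The NF-kB list lay at 1.41, 0.39 and 0.29 in CM plus DTM 1, 2 and 3 and at 1.59, 1.04 and 0.93 in CM. Without CM 1 and CM plus DTM 1, 26 interferon-stimulated, 7 interferon gamma, 12 NF-kB and 10 chemokine genes fell, while 1 chemokine, 8 proliferation and 6 cholesterol synthesis genes rose. With all libraries the chemokine, proliferation and cholesterol synthesis lists had 0 calls over all genes and were not called (list test adjusted p = 0.818, 0.57 and 0.694; adjusted p = 0.984 for each with an estimated correlation). The latter 2 were called without CM plus DTM 1 alone (adjusted p = 2.37e-11 and 0.000991), with medians of 0.94 against 0.55 and 0.33 against 0.15, but not without CM 1 alone (medians 0.29 and 0.19, adjusted p = 0.918 and 0.272).

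Of 19 osteoclast genes 1 rose and 4 fell when adjusted over the list alone, with a median of -0.34 (list test adjusted p = 0.0383; adjusted p = 0.786 with an estimated correlation), which was -0.60 without CM plus DTM 1. The proton pump subunit Tcirg1 stood at 361 ± 19.0 CPM against 581 ± 119, and the chloride channel Clcn7 at 137 ± 29.6 against 262 ± 75.7. Of 20 liver X receptor targets 5 fell when adjusted over the list alone, with a median of -0.48 (list test adjusted p = 0.0296; adjusted p = 0.786 with an estimated correlation), and without CM 1 that list was not called (median -0.29, adjusted p = 0.0724). Abcg1, singled out after its values were seen, stood at 40.8 ± 18.9 against 205 ± 124 CPM. The neutrophil list had a median of 1.60 with 0 calls and 1 fall when adjusted over the list alone (list test adjusted p = 0.0151; adjusted p = 0.984 with an estimated correlation), and the mesenchymal list a median of 0.43 with 0 calls by either count (list test adjusted p = 0.0292; adjusted p = 0.984 with an estimated correlation). Without CM 1, in which both cell types' genes were lowest, neither list was called (medians 1.07 and -0.04, adjusted p = 0.0632 and 0.838).

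By edgeR's quasi-likelihood test 0 of 15429 genes changed, although 4372 had an unadjusted p under 0.05 where chance gives 771, the smallest adjusted p of 0.0611 was shared by 621 genes, and DESeq2 called 2828 and limma-voom 0. The count was 1876 without CM plus DTM 2, 7 without CM plus DTM 1, 1 without control 3 or CM 3, and 776 without CM 1 and CM plus DTM 1.

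The comparison of CM plus DTM with control asked how far macrophages given both stood from untreated ones. Ifit1 rose by a log2 fold change of 4.54 (SE 0.88, adjusted p = 0.0348), which was 2.66 without CM plus DTM 1 (adjusted p = 0.0048), and Cx3cr1 fell by 4.17 (SE 0.73, adjusted p = 0.0251). Most interferon-stimulated genes rose here too, although without control 1 and 2 only 27 and 15 genes of any kind were called up. Ccl6, Mmp12, Mmp13 and Il1rn rose, and passed in all 9 fits that each lacked a library. The calls of Ifit1 (adjusted p up to 0.152) and Cx3cr1 (up to 0.0978) were lost without control 1, 2 or 3 or CM 2 or 3. That of Cx3cr1 was also lost without CM plus DTM 3. CM libraries are not compared here and enter only through the fit shared by all libraries. Calls lost without them, here and below, thus do not mean that a fold change rested on them.

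The largest rises were those of Cxcl3 (7.52), Slfn1 (7.18), Ifi213 (6.59), Ifi206 (6.19) and Ccl12 (5.81), a chemokine that attracts monocytes. Their order rested on CM plus DTM 1, without which Cxcl3 was the smallest of the 5 at 4.24 and Ifi206 the largest at 5.74. Cxcl3 stood at 574, 22.2 and 20.7 CPM in CM plus DTM 1, 2 and 3. The largest falls were those of Notch4 (-4.72), Cx3cr1, Olfml3 (-3.41), Snx29 (-2.67) and Pdpr (-2.49). Of these, Ifi206 alone passed in all 9 fits. Cxcl3, Ccl12, Olfml3, Snx29 and Pdpr were lost without control 1, 2 or 3 or CM 2 or 3 (adjusted p up to 0.169, 0.125, 0.162, 0.123 and 0.136), the latter 3 also without CM plus DTM 3, and Olfml3 and Snx29 without CM plus DTM 1. Slfn1 was lost without control 1, 2 or 3 (up to 0.0929), Ifi213 without control 1 or 2 (up to 0.0639), and Notch4 without control 2 or CM plus DTM 3 (up to 0.0558).

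Of the 54 interferon-stimulated genes 43 rose, 0 fell and 11 were not called, and 51 rose when adjusted over the list alone (list test adjusted p = 3.92e-38; adjusted p = 0.233 with an estimated correlation). Of 24 interferon gamma genes 13 rose and 0 fell, and 18 rose when adjusted over the list alone (list test adjusted p = 1.64e-13; adjusted p = 0.233 with an estimated correlation). Of 28 chemokines and receptors 8 rose and 1 fell, with 17 up and 1 down when adjusted over the list alone (list test adjusted p = 5.87e-06; adjusted p = 0.525 with an estimated correlation); that list lay 3.85 above the control mean in CM plus DTM 1 and 0.98 and 1.17 above it in CM plus DTM 2 and 3. Ccl6 rose by a log2 fold change of 4.83. Of 26 lipid-associated and tumour-associated genes 5 rose and 0 fell, with 9 up when adjusted over the list alone (list test adjusted p = 5.87e-06; adjusted p = 0.233 with an estimated correlation), including Mmp12 (2.67) and Fabp5 (1.98). Mmp13 (5.05) and the interleukin 1 antagonist Il1rn (2.55) rose as well. The chemokine list holds Cx3cr1 and the interferon-stimulated list Ifit1, which the study chose on these samples. Without CM 1, 13 chemokine genes rose. Without control 1, 2 and 3 only 27, 15 and 41 genes of any kind rose, so fewer than 43 interferon-stimulated genes can have passed there.

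Of 32 NF-kB genes 6 rose and 0 fell, with 10 up and 2 down when adjusted over the list alone (list test adjusted p = 0.00124; adjusted p = 0.655 with an estimated correlation). Of 20 alternative activation genes 3 rose and 0 fell, with 10 up and 1 down when adjusted over the list alone (list test adjusted p = 0.00768; adjusted p = 0.313 with an estimated correlation). Of 18 checkpoint and suppressive ligand genes 5 rose and 0 fell, with 8 up when adjusted over the list alone (list test adjusted p = 0.00245; adjusted p = 0.313 with an estimated correlation), among them Cd274 (3.04) and Lgals9 (1.97). Of 35 lysosome genes 2 rose and 0 fell, with 8 up and 1 down when adjusted over the list alone (list test adjusted p = 0.00245; adjusted p = 0.233 with an estimated correlation). Oxidative phosphorylation genes had 0 calls over all genes and 18 rises of 33 when adjusted over the list alone (list test adjusted p = 8.37e-07; adjusted p = 0.599 with an estimated correlation), and the 15 mitochondrially encoded transcripts 0 calls and 8 rises (list test adjusted p = 0.000606; adjusted p = 0.631 with an estimated correlation). Proliferation genes had 0 calls by either count and a median of -0.58 (list test adjusted p = 0.000365; adjusted p = 0.821 with an estimated correlation), which was -0.12 without CM plus DTM 1 (adjusted p = 0.916), where that list lay at -2.86 relative to the control mean. Without CM 1, 7 alternative activation genes, 5 lysosome genes and 2 oxidative phosphorylation genes rose. The call of Cd274 was lost without control 1, 2 or 3 or CM 2 or 3 (adjusted p up to 0.116), and that of Lgals9 without control 1, 2 or 3 (up to 0.0727).

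By edgeR's quasi-likelihood test 378 genes changed, 232 up and 146 down, and DESeq2 called 1981. The count was 30, 15 and 54 without control 1, 2 and 3, 740, 131 and 131 without CM 1, 2 and 3, and 1766 and 138 without CM plus DTM 2 and 3, and with total count scaling, which moved the median of all genes to -0.24, 176 rose and 273 fell. Of 37 called genes examined under the naming rule 7 passed in all 9 fits that each lacked a library, among them Ifi206, Mmp13, Mmp12, Il1rn, Fabp5 and Ccl6.

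**Figure D3:**
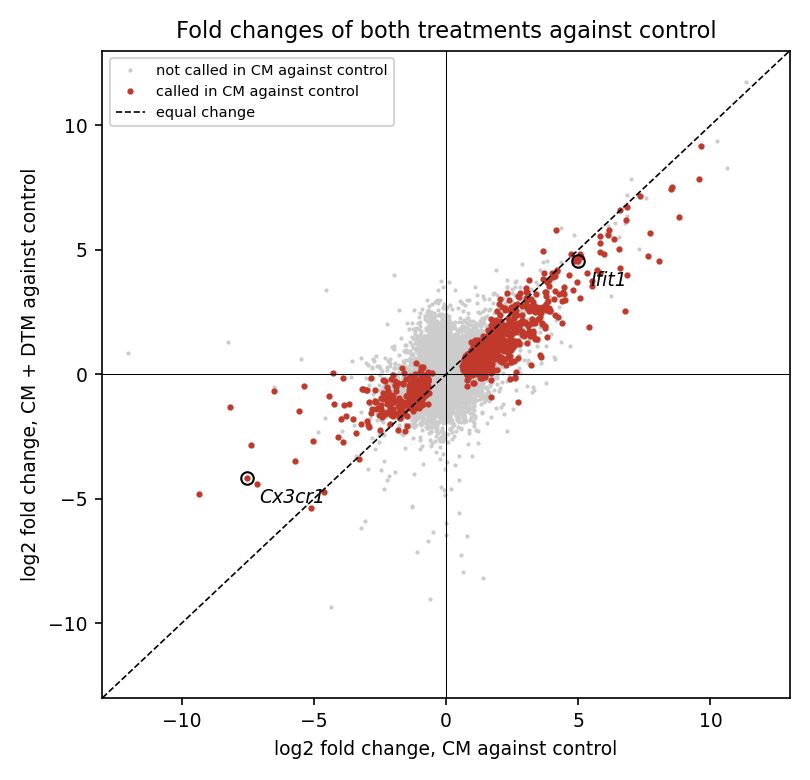
Each point is 1 of 15429 genes, with the log2 fold change of CM against control on the x axis and of CM plus DTM against control on the y axis; red points are the 865 genes called in CM against control and the dashed line marks equal change. Of the 865, 790 had a smaller change with DTM. The 865 were chosen by their change on the x axis, which by itself makes a smaller change on the y axis likely. Both axes share the 3 control libraries.

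Both comparisons with control used the same 3 control libraries. Their calls shared 195 genes that rose and 47 that fell, where independent lists of these sizes would share 9.37 and 2.29 and the mean of 100 simulations with no effect of either treatment was 0.01 and 0. The former leaves out the shared controls and the latter the effects, so neither measures how much of the overlap the shared controls add. The correlation of the fold changes across genes, which are not independent replicates, was 0.544 against a simulated mean of 0.495, and the covariance 0.469 against 0.143. CM against control and CM plus DTM against CM shared the 3 CM libraries in opposite roles. Of the 623 genes that rose with CM, 571 (91.7%) were lower with DTM than with CM alone, where simulations with no DTM effect gave 62.7% on average and at most 66.2%. Of the 242 that fell, 219 (90.5%) were higher, where simulations gave 70.1% on average and at most 73.8%. The correlation of these 2 sets of fold changes was -0.513 against a simulated mean of -0.246, and the covariance -0.433 against -0.145. There were 0 genes called in opposite directions in these comparisons by edgeR, against a simulated mean of 0.03 with no DTM effect. The simulations share libraries in the same way but draw each gene on its own. They leave out shifts that move many genes of a library together, as in CM 1 and CM plus DTM 1, so their limits are too narrow. With 3 libraries a group could not be split into parts of 2 or more, so part of each excess may come from the shared libraries. Slopes with no library shared are given under Other observations.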

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

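The fits with legacy = FALSE, with sample weights and without CM 1 and CM plus DTM 1 were chosen after seeing the data. The sample weights were 0.54, 3.63 and 1.23 in control, 0.17, 2.4 and 2.41 in CM, and 0.15, 0.68 and 4.16 in CM plus DTM. The weighted fit thus counted CM 1 and CM plus DTM 1 for little, and its CM plus DTM group rested mostly on CM plus DTM 3. All 9 libraries share 1 estimate of the spread, so leaving out a library can move calls even where a fold change hardly moves. The common dispersion, a measure of that spread, was 0.137 with all libraries. It was 0.151, 0.163 and 0.158 without control 1, 2 and 3, 0.155 and 0.153 without CM 2 and 3, and 0.096 without CM plus DTM 1. Without CM plus DTM 2 it was 0.136, so this measure alone does not follow the counts. Counts of changed genes depended strongly on the method, and the cause was not tested. For CM against control (865) they were 1937 by DESeq2, 1365 with the compared groups only, 2503 without CM 1 and CM plus DTM 1, 4649 with sample weights, and 256 to 1884 with a library left out. For CM plus DTM against CM (0) they were 2828, 1, 776, 6237 and 0 to 1876 in that order, 1 with total count scaling and 6 with legacy = FALSE. For CM plus DTM against control (378) they were 1981, 100, 1311, 5853 and 15 to 1766. Genes called in opposite directions (0) were 680 by DESeq2, 1 with total count scaling, 3 with legacy = FALSE, 500 without CM 1 and CM plus DTM 1, 2394 with sample weights and 0 to 146 with a library left out.

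Ifit1 and Cx3cr1 kept their direction in CM against control in every alternative run, with 4.81 to 5.13 and -7.92 to -6.9 as a library was left out. In CM plus DTM against CM, Ifit1 was -2.19 without CM 1 and CM plus DTM 1 and -2.25 with sample weights, past the threshold in both, and -2.36 to 0.05 with a library left out. Cx3cr1 there was 3.36 by DESeq2, 3.98 without CM 1 and CM plus DTM 1 and 3.59 with sample weights, past the threshold in each, and 2.68 to 3.78 with a library left out. Bst2 there lay between -0.19 (without CM plus DTM 1) and 0.64 with a library left out, and turned to -0.44 without CM 1 and CM plus DTM 1 and -0.30 with sample weights, and Ifi27l2a to -0.03 without CM 1 and CM plus DTM 1. The fit with sample weights and the fit without CM 1 and CM plus DTM 1 are not separate support for each other. Over 2257 values of other named genes under an alternative, 1953 kept their direction and side of the threshold. A further 253 lost the call, 47 gained it and 4 reversed, all 4 in CM plus DTM against CM.

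List calls were 0 in each comparison with an estimated correlation. For CM against control (16) they were 12 with fry in one direction, 25 in either and 14 to 16 with a library that stood apart left out; for CM plus DTM against CM (10), 5 and 13 with fry, 6 to 12, and 16 without CM 1 and CM plus DTM 1; for CM plus DTM against control (11), 8 and 18 with fry and 10 to 12.

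The library numbers were not taken to pair the samples, because the labels do not say that they do. In no pair of groups did every correlation exceed 0.1, a level that CM and CM plus DTM missed narrowly. Deviations of same-numbered libraries correlated at 0.032, 0.038 and -0.044 (control and CM), 0.297, 0.053 and 0.197 (control and CM plus DTM) and 0.127, 0.142 and 0.097 (CM and CM plus DTM). From the data, not the design, 6 of 9 libraries correlated best with their own number. The count that chance would give was not worked out, and the 9 outcomes are not independent. That count alone therefore cannot decide whether same-numbered libraries share structure. With the number as a block the counts were 675, 0 and 149. Relative to the control mean, library 1 had the lowest proliferation median of each group (-0.59, -2.04 and -2.86 in control, CM and CM plus DTM). Its NF-kB median was the highest of each (0.32, 1.59 and 1.41). Its neutrophil median was highest in control and CM plus DTM (0.99 and 1.95) and lowest in CM (-4.43). The labels do not say whether libraries of number 1 share an origin, so a source common to them cannot be told apart. Depth limits genes at hardly any counts, such as Nptx1 in CM at 0.0295 CPM.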

Other observations

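Tests of transcript length in CM plus DTM 1, of its depth and label, of the slopes library by library, and of oxidative phosphorylation genes without CM plus DTM 1 were chosen only after the result was seen. Single genes of lists that were not called also changed. Egr2, an early response transcription factor, rose with CM from 4.94 ± 2.16 to 49.6 ± 6.60 CPM and stood at 33.1 ± 20.9 CPM in CM plus DTM. Il7r, the interleukin 7 receptor, rose with CM from 28.5 ± 6.93 to 154 ± 44.6 CPM and stood at 66.2 ± 4.05 CPM in CM plus DTM. Plk2, a p53 target, rose with CM by a log2 fold change of 1.92. In CM plus DTM against control the growth factor Pdgfc rose by 2.38 and the integrin Itgav fell by 1.82. The call of Pdgfc was lost without control 1, 2 or 3 (adjusted p up to 0.0929), and that of Itgav also without CM 2 or 3 or CM plus DTM 3 (up to 0.104). The neutrophil gene Ngp stood at 0, 83.0 and 99.2 CPM in CM 1, 2 and 3, and the mesenchymal gene Acta2 at 36.6, 396 and 485 CPM, against 751 ± 118 CPM in control.

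CM plus DTM 1 stood apart from CM plus DTM 2 and 3, with an SD over genes of 1.18 on the log2 scale for its deviation from them. This SD was 0.47 to 0.68 for the control libraries and CM 2 and 3, 1.08 for CM 1, and 0.84 and 0.67 for CM plus DTM 2 and 3. Each deviation was taken from the mean of the other 2 libraries of the group. Those of CM 2 and 3 and of CM plus DTM 2 and 3 thus include a library that stood apart. A bias by transcript length or GC content does not account for the deviation of CM plus DTM 1 as a whole, since a trend over both removed 8.4% of its variance. Lower depth does not either, since the SD of the control libraries and CM 2 and 3, each thinned alone to 10% of its counts, rose to at most 0.94. Thinning all libraries to the lowest total moved no SD by over 0.01 and tested nothing. A swap of labels with another group is argued against by its highest correlation, 0.936 within its own group against 0.910 outside it, with all other libraries also closest to their own group. What made the library differ stays open, and no biological explanation was tested, because the design gives none within a group.

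The response to CM was weaker in CM plus DTM 2 and 3, which may reflect an effect of DTM or the sharing of libraries. With no library shared between the axes, held-out CM libraries had slopes of 0.59 to 0.72 on the CM response, and CM plus DTM 1, 2 and 3 had mean slopes of 0.63, 0.39 and 0.38. Sharing alone does not account for CM plus DTM 2 and 3, whose slopes reached at most 0.53 in any of 9 fits each. CM plus DTM 1 had a mean slope within the range of the CM libraries, with 0.49 to 0.82 over its 9 fits. This depended on the control library that it was set against. Against control 1 its slopes (0.7 to 0.82) lay above that of the CM library on the same axis (0.67 to 0.72). Against control 2 or 3 its slopes (0.49 to 0.65) lay below that of the CM library on the same axis (0.59 to 0.69). Whether its response was weaker therefore stays open. An effect of DTM is a candidate explanation that rests on 2 of 3 libraries, and why CM plus DTM 1 differed stays open.

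Oxidative phosphorylation genes were higher in CM plus DTM than in CM, and a bias by length or GC content could raise such short transcripts. Random lists matched on length, GC content and mean expression had a median of 0.44, and the list median of 0.73 exceeded 99.84% of 10000 such lists. The bias, as far as the matching captured it, does not account for the whole, though it may account for a part. How close the matches were was not measured, and length and GC content came from the longest transcript of each symbol. A remaining bias therefore cannot be excluded. The list minus its matched genes, compared after that percentile was seen, was 0.29, 0.17 and 0.22 in CM plus DTM and -0.20, -0.03 and -0.04 in CM. CM plus DTM 1 alone does not account for it, with a median of 0.54 without that library. Members of the list move together (estimated correlation 0.431), so the percentile describes these libraries and is not a p-value.

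Splits of 6 samples into 3 and 3 number 10, too few for a share under 0.05. For CM against control the real split gave 865 genes and the highest other 1, the count as large being 1. For CM plus DTM against control they gave 378 and 1, the count being 1. For CM plus DTM against CM they gave 0 and 1, and all 10 gave at least as many as the real one. A real count of 0 fixes that outcome in advance, so it tests nothing.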
